A study of Rattus norvegicus with 48 samples.

How the data were processed

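The series covers 48 one-colour microarrays from male adult Sprague-Dawley rats, an outbred laboratory strain, 24 hybridised with RNA from whisker hair follicles and 24 with RNA from whole blood. Per the labels, the rats were 9 to 10 weeks old and weighed 350 to 400 g. They were anaesthetised with 3% isoflurane for 8 min and exposed once, head only, to a shockwave from an Advanced Blast Simulator, a tube that makes a pressure wave like that of an explosion. The positive phase lasted about 4 ms at a static overpressure of 15, 20, 25 or 30 psi, and sham rats were the comparison. Up to 20 whisker follicles and 5 ml of blood were taken 1 day later, total RNA was extracted with Trizol, and the RNA was labelled with Cy3. The labels state 5 animals per group, and 8 of the 10 groups hold 5 arrays here; the hair 20 psi and the blood 15 psi groups hold 4. Rats are named below by the numbers of their labels.

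Per the file headers, the authors scanned the arrays on 1 channel and extracted them with Agilent Feature Extraction 10.7. The scanner files hold an intensity per spot on a linear scale, per the file headers, and the main values started from the processed signal, in which that program had subtracted the background, detrended the array and raised low signals to a surrogate. The array's grid was annotated against the rn4 assembly, per the file headers, whereas the gene names used here came from a table of the GRCr8 assembly, so no coordinates are given. The authors' deposited value table holds log2 values. Its column medians lay between 6.801 and 6.827, close but not equal, and the values appeared to be quantile-normalized over all 48 arrays. Within each array they were ordered as the median minus the background signal (rank correlation of 1). The software behind that table is not given in the sources used here, and it served as an alternative only.

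Each array holds 62976 spots, of which 58717 are not controls; these are 30367 probes, 13137 spotted once, 15840 in duplicate and 1390 at 10 places. A RefSeq accession stands on 23402 probes, an Ensembl transcript on 2082, another accession on 652 and a probe name alone on 4231. Through the RefSeq accession, 18643 probes received 1 of 15637 gene symbols; the other 11724 probes were tested and counted without a name. Control spots and the 23989 spots marked as outliers over all arrays were left out, which cost 41 probe values, and spots of a probe were averaged. The 1 saturated spot was kept.

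Values were log2 of the processed signal minus the array's 75th percentile. A probe was tested in a tissue where it lay well above background on at least 3 arrays of at least 1 group. The contrasts were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with version 1.17.8 of data.table and 2.0.0 of jsonlite. All 24 arrays of a tissue shared 1 estimate of the spread; each intensity was set against sham, the mean of the 4 exposed groups was set against sham (any blast), and a linear trend per psi was fitted over the exposed groups. Both tissues were fitted together for the difference of their any-blast responses and for hair against blood in sham rats. The two-sided p-values were adjusted by Benjamini-Hochberg over the probes tested, and a probe was called at an adjusted p under 0.05. Exposed groups were compared with the same sham arrays, so their values are not independent of each other.

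Gene lists of cell type markers and pathways, 38 in number, were tested with limma's camera at a preset inter-gene correlation of 0.01, with the brightest probe of each gene, for the any-blast and trend contrasts together; lists with fewer than 5 tested genes were left out, which kept 36 in hair and 38 in blood. Camera compares a list with all other genes tested. It was repeated with a correlation estimated from the residuals, and a list's score (the mean over its genes, relative to the sham mean) was tested by permuting whole rats, exactly over 42504 assignments for any blast and with 100000 reshuffles for the trend. These permutations were not kept within slides or scan days. For each list, members were also adjusted over the list alone.

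The design, the lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where the text says that a choice was made after seeing the data. Under that rule, the probe with the smallest p stood for a gene, and in each tissue and contrast the 10 genes with the largest fold in each direction among those called were to be named (5 for the trend); where fewer than 5 were called, the genes with the smallest p up to 5 were named, as values that did not pass. Called lists were given up to 4 members with the smallest p and other lists up to 3 of their brightest members. The between-tissue difference was given 5 genes per direction, and hair against blood in sham rats the 3 brightest members of the hair shaft, outer root sheath, erythroid and neutrophil lists. Where a gene lay at or below background on all arrays of a group, the fold is a bound, written as at least N-fold: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own.

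The arrays lay on 6 slides of 8 arrays, scanned on 2 days, and every group was split over both days. The main fits held no covariate. Slide and scan day were fitted as covariates in alternative fits, and results were also given within each. Values within a slide are mean list scores of its exposed rats minus those of its sham rats. They rest on 1 sham array per slide in blood and on 1 or 2 in hair, and only slides with both kinds of rat are given. Alternatives fixed beforehand were quantile normalization, the value table, no filter or a stricter one on dim probes, slide as a random or fixed block, array weights, the series of rat numbers (under 500 against over 500) as a covariate or the rats under 500 alone, the compared groups alone, and each array left out in turn. Chosen after seeing the data were scan day, the removal of the 2 arrays that stood apart, the permutation of whole rats, and normexp (offset 50) on the median signal in place of the mean signal, which the files analysed here do not list. Hair and blood arrays with the same rat number come from the same animal per the labels, which holds for 10 rats; the deviations of the 2 tissues of a rat from their group means correlated between -0.13 and 0.27, with a median of 0, over 19169 probes.

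The steps were tested on simulated data: the residuals of the real arrays were reshuffled and 200 genes were changed, in 10 data sets per comparison. For any blast, 22.6% of the genes changed 1.5-fold, 57.0% of those changed 2-fold and 85.4% of those changed 3-fold were called in hair (20667 probes), and 13.2%, 58.0% and 89.8% in blood (18003 probes). For single intensities, 3-fold changes were called for 69.6% to 76.2% of genes in hair and for 71.6% to 77.6% in blood. False calls per data set averaged 0.7 in hair and 6.3 in blood for any blast and reached 26.9 for hair at 20 psi. With no change simulated, camera at its preset correlation still called a mean of 8.2 lists in hair and 8.8 in blood, in 10 of 10 data sets each, and called none (0 of 10) with the estimated correlation. The median 95% confidence interval of a probe reached 0.43 in hair and 0.45 in blood on the log2 scale to either side for any blast (1.35-fold and 1.37-fold), and 0.55 to 0.60 for a single intensity; the number of arrays limits this precision.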

Results

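Gene expression was measured 1 day after a single head-only shockwave in whisker hair follicles and in whole blood, the 2 tissues sampled in this model of mild traumatic brain injury. Each tissue has 24 arrays in 5 groups, sham and static overpressures of 15, 20, 25 and 30 psi. Groups hold 5 rats, except hair at 20 psi and blood at 15 psi with 4. The comparisons ask which transcripts differ between exposed and sham rats, whether they follow the overpressure, and whether the 2 tissues differ in response. The 75th percentile of the signal ranged from 245.1 to 940.1 (median 613.75) on hair arrays and from 130.8 to 361.9 (median 195.6) on blood arrays. Between 50.8% and 71.8% of probes lay well above background in hair, and between 42.7% and 80.9% in blood. The brightest blood array, from 20 psi rat 518, read high at probes that were not well above background on any other blood array, a choice of probes that favours such a reading. The dimmest hair array, from sham rat 384, correlated least with the other hair arrays (median 0.927). Scan day alone, tested by limma with Benjamini-Hochberg adjustment, accounted for 1356 probes in blood, 1275 higher on day 2 and 81 lower, and for 0 in hair. The series of rat numbers accounted for 7 probes in hair.

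In sham rats, follicles and blood differed in the genes of their own cell types. Krt34, a keratin of the hair cortex, was 2220-fold higher in hair (log2 difference 11.12 ± 0.39 SE, n = 5 and 5, limma adjusted p = 2.09e-28). The keratin-associated proteins Krtap15-1 and Krtap1-5 were 537-fold (adjusted p = 5.37e-26) and 73.4-fold higher (adjusted p = 4.2e-24). Krt6c and Krt17 of the outer root sheath were not well above background in blood and were at least 4730-fold and at least 4070-fold higher in hair (adjusted p = 6.73e-32 and 2.05e-28). Krt14, of basal keratinocytes, was 261-fold higher (8.03 ± 0.29). Alas2, the first enzyme of heme synthesis in red cell precursors, was 11900-fold lower in hair (-13.54 ± 0.40, adjusted p = 2.52e-31). The globins Hba-a1 and Hbb-b1 were 272-fold (-8.09 ± 0.70) and 1970-fold lower (-10.94 ± 1.19, adjusted p = 2.87e-11). Hbb-b1 varied widely between follicle samples, at 0.87 ± 2.85 (SD, n = 5) against 11.82 ± 0.52 in blood. Among neutrophil genes, the calprotectin subunit S100a9 was 167-fold lower in hair (-7.38 ± 0.55, adjusted p = 2.47e-16) and Retnlg 241-fold lower (-7.91 ± 0.33). Padi4, which converts arginine to citrulline in proteins, was 22.4-fold higher (4.48 ± 0.32).

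By list, 12 of 13 hair shaft genes were called higher in hair and 1 lower, with a median log2 difference of 9.21. All of the inner root sheath genes, 9 of 9, were higher (median 5.92, or 5.27 with genes at background taken at their bound). Of the outer root sheath genes 9 of 12 were higher and 2 lower (7.79), and of the suprabasal epidermal genes 6 of 10 were higher and 2 lower (4.35, or 3.73 with bounds). Melanocyte genes were higher in 6 of 8 cases and lower in 2 (2.30). Of the blood cell lists, 17 of 18 erythroid genes were lower in hair and 1 higher (-8.81, or -8.68 with bounds). Neutrophil genes were lower in 16 of 18 cases and higher in 2 (-3.96, or -3.80), and monocyte genes lower in 12 of 14 and higher in 1 (-4.27, or -4.24). T cell genes were lower in 16 of 17 cases (-5.19, or -5.09), B cell genes in 15 of 15 (-4.45), natural killer genes in 14 of 14 (-4.28, or -4.11) and platelet genes in 14 of 14 (-6.19). Endothelial genes were lower in 6 of 6 cases (-4.37, or -4.24), skeletal muscle genes in 8 of 13 with 1 higher (-1.88), and adipocyte genes in 4 of 6 with 1 higher (-2.21). Dermal fibroblast genes were higher in 5 of 8 cases and lower in 2 (1.67, or 1.21). Schwann cell genes were higher in 4 of 13 cases and lower in 7 (-0.84), and Merkel cell genes higher in 1 of 6 and lower in 3 (-0.58).

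Over all 22786 probes, limma called 17730 between the sham tissues, 7858 higher and 9872 lower in hair, with a smallest adjusted p of 7.97e-40. Of these, 1857 were at or below background on all 5 blood arrays and 1302 on all 5 hair arrays. With slide as a fixed block, 17410 were called. The median over all probes was -0.24, and the split of higher against lower calls depended on the scaling and on the filter on dim probes. It was 9769 against 7788 after quantile normalization (median 0.29), 6457 against 12407 with normexp (-0.57), and 7870 against 17088 without a filter on dim probes (-1.23).

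**Figure D1:**
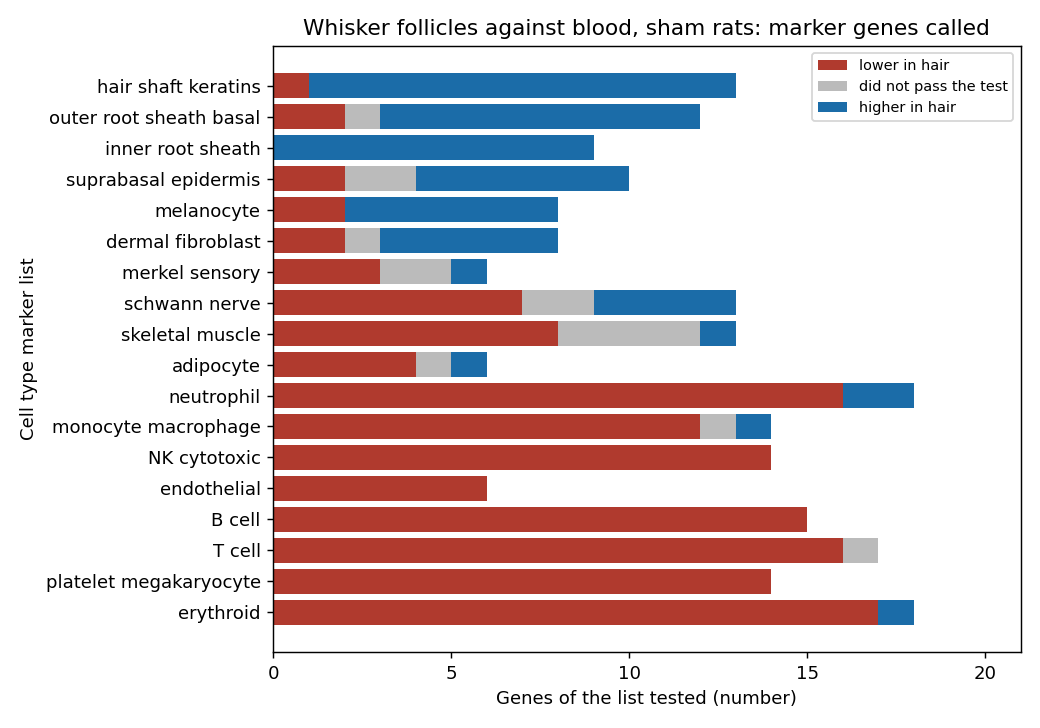
Number of genes per cell type list (horizontal axis) that limma called higher in hair, lower in hair or not at all, in 5 hair against 5 blood arrays of sham rats. Hair shaft genes lie mostly on the higher side (12 of 13) and erythroid genes on the lower side (17 of 18).

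In hair, genes of the cell cycle stood higher in exposed than in sham rats as a group. Of 31 genes 29 had a positive difference, with a median of 0.22 on the log2 scale, and 14 of 19 exposed rats lay above the sham mean. Among them were the mitotic kinase Plk1 (0.27 ± 0.15 SE), the proliferation marker Mki67 (0.27 ± 0.15) and the replication helicase subunits Mcm7 (0.27 ± 0.15) and Mcm3 (0.22 ± 0.13), none of which passed alone. Camera at its preset correlation called the list (adjusted p = 6.25e-05). The adjusted p was 0.937 with an estimated correlation, and the exact permutation of whole rats gave p = 0.238. The trend with overpressure was also called, at a median of 0.023 per psi with 29 of 31 genes positive (preset adjusted p = 1.06e-12). Its adjusted p was 0.937 with an estimated correlation, and its permutation p was 0.0568. Kif20a (0.037 ± 0.014), Tpx2 (0.045 ± 0.017), Ccnb1 (0.046 ± 0.018) and Plk1 (0.029 ± 0.012), all genes of mitosis, had the smallest p. The mean score was 0 ± 0.11 (SD) in sham rats, -0.09 ± 0.20 at 15 psi, 0.26 ± 0.25 at 20 psi, 0.25 ± 0.28 at 25 psi and 0.31 ± 0.41 at 30 psi.

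Within the scan days, the any-blast median of the hair cell cycle genes was 0.17 and 0.25, and the trend 0.019 and 0.029 per psi. Within the slides that held both kinds of rat, with 1 or 2 sham arrays each, the score of exposed rats differed from sham by 0.07, 0.15, 0.23 and 0.08. With slide as a fixed block the medians were 0.15 (adjusted p = 0.0257) and 0.027 (adjusted p = 3.67e-12). The series of rat numbers was unevenly spread over the groups, with rats under 500 making up 4 of 5 sham rats and 4 of 5 at 15 psi, but 2 of 4 at 20 psi and 2 of 5 each at 25 and 30 psi. With the series as a covariate the medians were 0.18 (adjusted p = 0.012) and 0.021 (8.12e-10). In the rats numbered under 500 alone the any-blast call was lost (0.13, adjusted p = 0.231) and the trend turned to -0.002 (0.593).

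Ribosomal protein genes of hair stood lower in exposed rats. For any blast 45 of 47 had a negative difference, with a median of -0.10, and 7 of 19 exposed rats lay above the sham mean. Rpl19 (-0.26 ± 0.15), Rpl5 (-0.21 ± 0.12), Rplp1 (-0.24 ± 0.17) and Rps20 (-0.17 ± 0.13), all parts of the cytosolic ribosome, had the smallest p. The list was called at the preset correlation (adjusted p = 0.00023) but had an adjusted p = 0.937 with an estimated correlation, and the exact permutation p was 0.325. Along the overpressure 42 of 47 had a negative slope, with a median of -0.006 per psi, led by Rps3 (-0.070 ± 0.043), Rplp1 (-0.016), Rps29 (-0.013) and Rps20 (-0.012). That trend had a preset adjusted p = 0.000701, an adjusted p = 0.937 with an estimated correlation, and a permutation p of 0.41. Within the scan days the any-blast median was -0.14 and -0.01 and the trend -0.004 and -0.009. The slides gave score differences of -0.09, 0.11, -0.14 and -0.13. Slide as a fixed block ended the any-blast call (-0.06, adjusted p = 0.11) and kept that of the trend (-0.007, adjusted p = 4.6e-05). The any-blast call was also lost without sham rat 381 (-0.08, adjusted p = 0.0584), 382 (-0.06, 0.319) or 384 (-0.04, 0.302). The call of the trend was lost without 15 psi rat 387 (-0.005, adjusted p = 0.0675) or 30 psi rat 526 (-0.002, 0.437). The any-blast call was also absent after quantile normalization (-0.02, adjusted p = 0.206), with normexp (-0.04, 0.792), in the value table (0.04, 0.677) and with array weights (0.03, 0.969). The same holds within scan day 2 (adjusted p = 0.805), with the series of rat numbers as a covariate (-0.02, 0.577) and in the rats under 500 (0.02, 0.997). That of the trend was absent after quantile normalization (0, adjusted p = 0.994), within scan day 1 (0.0921), with the series as a covariate (0.001, 0.937) and in the rats under 500 (0.003, 0.8).

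Nuclear-encoded respiratory chain subunits of hair had negative slopes with overpressure in 46 of 52 cases, with a median of -0.009 per psi. The complex I subunits Ndufa2 (-0.019 ± 0.009) and Ndufa1 (-0.017 ± 0.010), the complex IV subunit Cox7c (-0.038 ± 0.021) and the complex II subunit Sdhd (-0.020 ± 0.012) had the smallest p. The trend was called at the preset correlation (adjusted p = 1.69e-06), with an adjusted p = 0.937 with an estimated correlation and a permutation p of 0.258. Its slope was -0.001 and -0.013 within the scan days and -0.009 with slide as a fixed block (adjusted p = 3.91e-07). Exposed rats differed from sham by -0.09, 0.05, -0.12 and -0.01 within the slides, and for any blast the list was not called (-0.02, adjusted p = 0.16). The call of the trend was lost after quantile normalization (-0.002, adjusted p = 0.393) and with the series of rat numbers as a covariate (-0.003, 0.138). It was also absent within scan day 1 (adjusted p = 0.304) and in the rats under 500, where the slope turned (0.003, 0.383).

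Hypoxia-inducible and glycolytic genes of hair stood lower in exposed rats, with 23 of 28 negative, a median of -0.11 and 5 of 19 rats above the sham mean. The mitophagy receptor Bnip3 (-0.36 ± 0.17), the glycolytic enzymes Aldoa (-0.28 ± 0.13) and Pkm (-0.31 ± 0.19) and Pdk1 (-0.28 ± 0.20), a kinase that restrains pyruvate dehydrogenase, had the smallest p. The preset adjusted p was 0.0354, with an adjusted p = 0.937 with an estimated correlation and an exact permutation p of 0.236. The median was -0.07 and -0.08 within the scan days, and the slides gave score differences of -0.11, -0.18, 0.04 and -0.10. Slide as a fixed block ended the call (-0.07, adjusted p = 0.11), as did scan day as a covariate (-0.09, 0.0621), and neither scan day alone gave it (0.286 and 0.144). Nor was it made after quantile normalization (-0.08, adjusted p = 0.129), with normexp (-0.07, 0.769), in the value table (-0.06, 0.269), with array weights (-0.06, 0.717) or without a filter on dim probes (-0.10, 0.184). The trend of this list, not called over all arrays (-0.005 per psi, 0.174), was called lower with slide as a fixed block (adjusted p = 0.0307) and with the series of rat numbers as a covariate (0.0494). The any-blast call was also lost without sham rat 382 (-0.05, adjusted p = 0.506), 383 (-0.06, 0.0507) or 384 (-0.09, 0.216). The same holds for 15 psi rat 387 (-0.08, 0.0675), 20 psi rat 394 (-0.09, 0.0541), 25 psi rat 395 (-0.10, 0.081) and 30 psi rat 526 (-0.08, 0.0574). In the called hair lists, 0 members passed when adjusted over the list alone, and 0 over all genes tested.

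**Figure D2:**
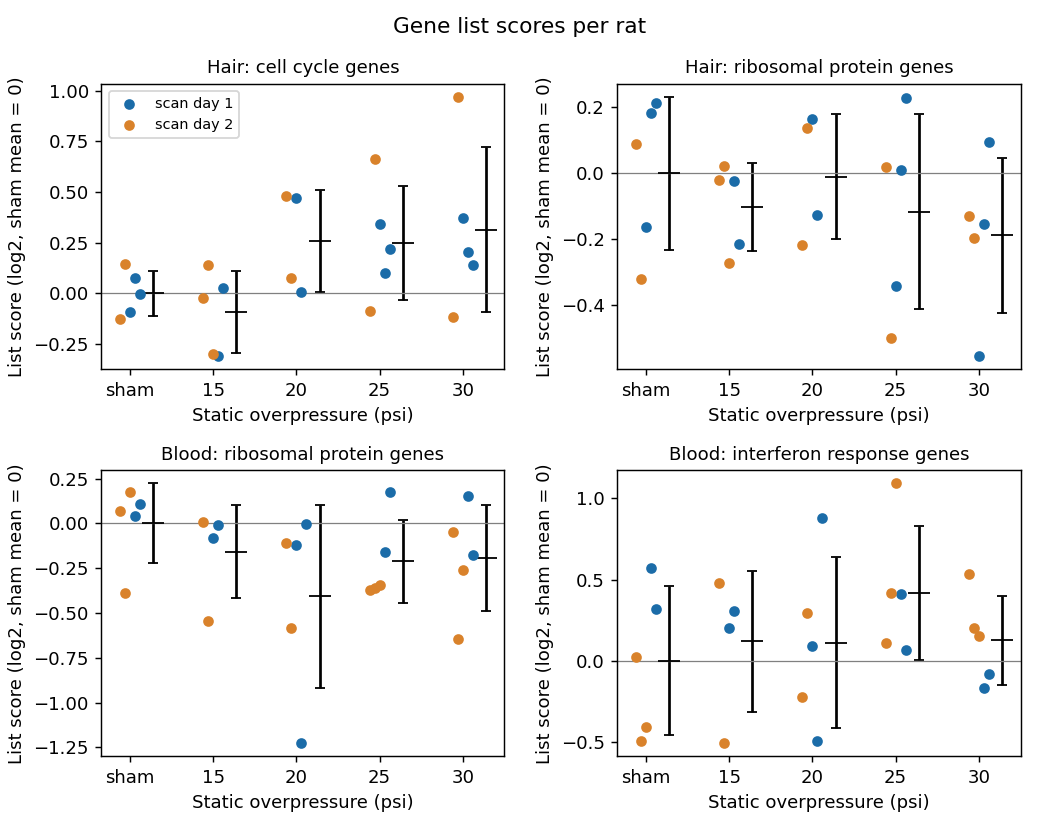
Score of 4 gene lists per rat (vertical axes, mean log2 value relative to the sham mean) against static overpressure in psi (horizontal axes), with points coloured by scan day and bars for the group mean ± SD. The hair cell cycle score at 30 psi ranges from -0.11 to 0.97, and the blood ribosomal protein score at 20 psi from -1.23 to 0.

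Markers of the follicle's own cell layers were not called for any blast over all hair arrays, but some were under other settings. Hair shaft genes had a median of 0.22 (camera adjusted p = 0.222, 10 of 13 positive), with Krt81 at 0.36, and inner root sheath genes 0.20 (adjusted p = 0.41, 9 of 9 positive), with Krt25 at 0.02 ± 0.28 and Krt27 at 0.20 ± 0.30. Suprabasal epidermal genes had a median of 0.23 (adjusted p = 0.083) and melanocyte genes 0.16 (0.894). Outer root sheath genes (-0.13, adjusted p = 0.372) and dermal fibroblast genes (-0.13, 0.656) had negative medians. The direction of the hair shaft and melanocyte lists rested on sham rat 384. Without it, both were called lower in exposed rats at the preset correlation (adjusted p = 0.00413 and 0.0281). Within scan day 1 hair shaft genes were called higher (0.56, adjusted p = 0.000806) and within scan day 2 lower (-0.35, 0.00274), as were melanocyte genes on day 2 (-0.80, 0.000135). Rat 384 was among the 3 hair sham arrays of day 1, so the higher call there includes it. The opposite signs therefore do not show a difference between the scan days. With all arrays, hair shaft genes were called higher with slide as a fixed block (adjusted p = 0.0257), after quantile normalization (0.00257), in the value table (0.0257) and with normexp (0.0413). Inner root sheath genes were so with slide as a fixed block (adjusted p = 0.0388), with normexp (0.0413) and in the rats under 500 (0.00678), and for the trend with the series of rat numbers as a covariate (0.0494). Suprabasal genes were so with normexp (adjusted p = 0.0413), in the value table (0.0265) and within scan day 2 (0.0164). These calls hold at the preset correlation, and with an estimated one the smallest adjusted p of a hair list over all arrays was 0.937. Signalling genes of the hair cycle had a median of 0.19 (adjusted p = 0.379, 23 of 32 positive), with Dlx3 at 0.36, Notch1 at 0.18 and Ovol1 at 0.24. They were called higher within scan day 1 alone, which also includes rat 384 (0.35, adjusted p = 0.0181), against -0.08 within scan day 2.

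Of the stress pathways of hair, heat shock genes had a median of 0.12 (adjusted p = 0.0974), with the chaperones Hspa8 at 0.08 and Hspe1 at 0.20. Endoplasmic reticulum stress genes had one of 0.06 (adjusted p = 0.233), with the chaperone Hspa5 at 0.35 ± 0.17, and immediate early genes one of 0.14 (0.382), with Junb at 0.15 ± 0.20. The median was 0.06 for p53 targets (adjusted p = 0.445), -0.02 for glucocorticoid-induced genes (0.636) and 0.08 for clock genes (0.669), with Cdkn1a at -0.17 and Dbp at 0.25. Heat shock genes were called higher with normexp (adjusted p = 0.00213), in the value table (0.0393) and without a filter on dim probes (0.0129), and endoplasmic reticulum stress genes with normexp (0.016) and in the rats under 500 (0.024). Immediate early genes were called higher for the trend with normexp (adjusted p = 0.0177) and in the value table (0.0365). Interferon-stimulated genes had a median of -0.07 (adjusted p = 0.252, 16 of 23 negative), with a call within scan day 1 (-0.29, 0.002) against 0.19 within scan day 2. Their trend was not called over all arrays (-0.009 per psi, adjusted p = 0.0781). It was called lower with slide as a fixed block (adjusted p = 0.0257), after quantile normalization (0.0104), with normexp (0.00915), in the value table (0.0257) and with the series of rat numbers as a covariate (0.0367). The same holds without a filter on dim probes (adjusted p = 0.0418), with the mean over the probes of a gene (0.038), without rat 384 (0.0407) and within scan day 1 (0.0181). With an estimated correlation its adjusted p over all arrays was 0.937. Within scan day 2 the trends of neutrophil genes (-0.048, adjusted p = 0.0301) and of genes of neurodegeneration pathways (0.0343) were called lower. In the inflammatory list the median was 0.04 while mean and test were negative (-0.01, adjusted p = 0.826). There 1 member passed when adjusted over the list alone, the NF-kB inhibitor Nfkbia (-0.58 ± 0.18), and 0 passed over all genes tested. Markers of brain injury, neuronal and glial genes followed in body fluids, had a median of -0.05 but a mean of 0.04 and a positive test (adjusted p = 0.962). Of them, Sptan1 differed by 0.21 ± 0.11, Uchl1 by 0.70 ± 0.43 and Tubb3 by 0.60 ± 0.58.

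No single probe was called at any overpressure in hair, by limma over 20673 probes. At an unadjusted p under 0.05 there were 192 probes at 15 psi (72 higher), 679 at 20 psi (321 higher), 1127 at 25 psi (628 higher) and 610 at 30 psi (316 higher), with 0 called in each. For any blast there were 705 (392 higher, 0 called) and for the trend 426 (336 higher, 0 called). The smallest adjusted p was 1, 0.507, 0.895, 1, 0.847 and 1 in that order. With slide as a fixed block the counts were also 0, and for any blast and the trend they were 0 within each scan day. The unadjusted counts depended on single rats. Without sham rat 384 they were 1220 at 20 psi, 2496 at 25 psi and 1374 for any blast, with 317 at 15 psi, and without sham rat 382 there were 391 at 15 psi. Low extremes were 400 at 20 psi without rat 390, 607 at 25 psi without rat 523 and 225 for the trend without 30 psi rat 526. The processing moved them as well, with 0 called each time. Array weights gave 965 at 15 psi, 2424 at 20 psi, 1759 at 25 psi, 1745 for any blast and 1327 for the trend. Slide as a fixed block gave 124 at 15 psi, and normexp 636 at 25 psi and 144 for the trend. The trend had 221 after quantile normalization and 242 in the value table. Without a filter on dim probes there were 430 at 15 psi, 1080 at 20 psi and 766 for the trend, and with the stricter filter 119, 433 and 178. The groups compared alone gave 558 at 25 psi, and the rats under 500 gave 1252 at 20 psi, 1797 at 25 psi, 1500 for any blast and 124 for the trend. Within the scan days, with fewer arrays, the counts ran from 120 to 987.

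The genes named for hair from here on had the smallest p and did not pass. For any blast, the higher side held Lyl1, a transcription factor of blood formation (0.75 ± 0.19 SE, adjusted p = 0.847), and the receptor tyrosine kinase Erbb2 (1.02 ± 0.26, 0.847), which lay above background on 1 of 5 sham and 17 of 19 exposed arrays. Rbbp5, a subunit of histone H3 lysine methyltransferases, differed by 0.33 ± 0.09 (adjusted p = 0.995). Dnd1, a germ cell RNA-binding protein, was at least 1.43-fold and the ferritin receptor Scara5 at least 1.57-fold higher (adjusted p = 0.995 and 1). Both were at background in 5 of 5 sham rats and above it in 8 and 7 of 19 exposed rats, and with normexp their differences turned to -0.04 and -0.05. On the lower side (adjusted p = 0.847 for all) were the protein kinase A inhibitor Pkib (-0.83 ± 0.17), the histamine H4 receptor Hrh4 (-0.88 ± 0.19), the adhesion receptor Adgrg2 (-0.67 ± 0.15), Nus1 of dolichol synthesis (-0.74 ± 0.18) and Depp1 (-1.79 ± 0.43). Only 1 of the 2 probes of Nus1 had this direction. Pkib lay at -0.02 ± 0.41 (SD) in sham and -0.84 ± 0.36 in exposed rats, and Depp1 at -1.09 ± 1.55 and -2.88 ± 0.65. Depp1 depended on sham rat 506, without which limma called it for any blast (-2.43, adjusted p = 0.0106) and at 25 psi (-2.82, 0.0216).

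At 15 psi in hair the adjusted p was 1 for all genes named. On the higher side were Dnd1 (at least 1.53-fold), Banp (0.64 ± 0.23), the prostaglandin E receptor Ptger3 (0.88 ± 0.32), the EGR corepressor Nab2 (0.53 ± 0.20) and the clock repressor Cry1 (0.42 ± 0.16). On the lower side were the death receptor Tnfrsf21 (at least 2.12-fold, by 1 of its 2 probes), the initiator caspase Casp9 (-1.08 ± 0.31), Depp1 (-1.70 ± 0.54), Hrh4 (-0.70 ± 0.24) and Nfkbia (-0.64 ± 0.22). At 20 psi, Dnd1 was at least 2.42-fold higher, above background on 4 of 4 exposed and 0 of 5 sham arrays (adjusted p = 0.507). It stood beside Lyl1 (1.28 ± 0.25, adjusted p = 0.507), the carnitine palmitoyltransferase Cpt1b (0.59 ± 0.15), the potassium channel Kcnj14 (0.67 ± 0.19) and Ctrl (0.85 ± 0.24). The lower side held Pkib (-1.12 ± 0.23, adjusted p = 0.507), Tex19.2 (-0.75 ± 0.17, 0.908), Diras1 (-0.76 ± 0.18, 0.908), Hrh4 (-1.09 ± 0.26, 0.983) and Nus1 (-0.93 ± 0.24, 0.999).

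At 25 psi in hair the adjusted p was 0.895 for all genes named. The adhesion molecule Alcam lay at 0.79 ± 0.18 (SD) in sham and 1.51 ± 0.17 in exposed rats (0.72 ± 0.15 SE). Dnai7 (0.81 ± 0.19), the tight junction protein Cldn19 (1.14 ± 0.28), the microtubule-binding Eml4 (0.90 ± 0.23) and Agrp (at least 1.91-fold) were also on the higher side. Ntmt1 (-0.74 ± 0.17), Pkib (-0.91 ± 0.22), Depp1 (-2.18 ± 0.54), Nudt17 (-1.26 ± 0.34) and Tbc1d17 (-0.52 ± 0.14) were on the lower side. At 30 psi the adjusted p was again 1. Magi3 (0.67 ± 0.17), the serine protease Tmprss11d (1.00 ± 0.28), Scara5 (at least 1.80-fold, but -0.04 with normexp), Eml4 (0.81 ± 0.23) and Nmral1 (0.62 ± 0.18) led the higher side. Nudt17 (-1.54 ± 0.34), Adgrg2 (-0.79 ± 0.19), Tex19.2 (-0.65 ± 0.16), Hrh4 (-0.97 ± 0.24) and the chaperone Erp29 (-0.45 ± 0.12) led the lower side. For the trend (adjusted p = 1), positive slopes per psi were those of the spectrin-binding Add1 (0.049 ± 0.014), Magi3 (0.035 ± 0.011) and Nxph3 (0.059 ± 0.018). Tnfrsf21 and the defensin Defb21 also had a positive sign, but lay above background on 6 and 3 of 19 exposed arrays and on 0 at 15 psi, so no slope is given. Only 1 of the 2 probes of Tnfrsf21, of Add1 and of Slc49a3 had the direction given. Negative ones were those of Slc49a3 (-0.046 ± 0.014), Nudt17 (-0.066 ± 0.022), Ppp1r1b (-0.062 ± 0.020), the calcium store protein Casq2 (-0.117 ± 0.039) and Pfdn1 (-0.021 ± 0.008).

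In blood, ribosomal protein genes stood lower in exposed than in sham rats. Of 47 genes 47 had a negative difference, with a median of -0.25, and 3 of 19 exposed rats lay above the sham mean. Rpl13 (-0.40 ± 0.19), Rpl32 (-0.35 ± 0.18), Rplp1 (-0.36 ± 0.19) and Rps15 (-0.31 ± 0.17) had the smallest p. The list was called at the preset correlation (adjusted p = 5.48e-13). Its adjusted p was 0.998 with an estimated correlation, and the exact permutation of whole rats gave p = 0.129. The score was 0 ± 0.22 (SD) in sham rats, -0.16 ± 0.26 at 15 psi, -0.41 ± 0.51 at 20 psi, -0.21 ± 0.23 at 25 psi and -0.20 ± 0.30 at 30 psi, and without rat 518 the any-blast median was -0.19. The median was -0.21 and -0.28 within the scan days and -0.31 with slide as a fixed block (adjusted p = 1.51e-19). The slides, each with 1 sham array, gave score differences of -0.20, -0.11, -0.61, -0.06 and -0.57. Within scan day 1 alone the list was not called (adjusted p = 0.134). The size of the shift depended on the scaling, with a median of -0.07 after quantile normalization (adjusted p = 0.0153) and -0.06 in the value table (0.0369). Its trend was not called over all arrays (0.001 per psi, adjusted p = 0.898), but was called lower after quantile normalization (1.11e-08) and in the value table (4.3e-11). With an estimated correlation the adjusted p of the trend was 0.998. Over all blood probes the any-blast median was -0.03, against -0.07 with the stricter filter on dim probes and 0.06 without a filter. Camera compared each list with all other genes, whatever their brightness. Whether this list or the other blood lists differed from genes of similar brightness was not tested.

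Respiratory chain subunits of blood also stood lower, with 42 of 52 negative, a median of -0.14 and 6 of 19 rats above the sham mean. The complex I subunit Ndufb8 (-0.50 ± 0.20), the complex IV subunits Cox7a2 (-0.39 ± 0.20) and Cox7b (-0.47 ± 0.25) and the ATP synthase subunit Atp5po (-0.35 ± 0.19) had the smallest p. The preset adjusted p was 9.5e-05, with an adjusted p = 0.998 with an estimated correlation and an exact permutation p of 0.28. The median was -0.12 and -0.19 within the scan days and -0.19 with slide as a fixed block (adjusted p = 4.7e-08), and -0.09 without rat 518. The slides gave score differences of -0.11, -0.06, -0.41, 0.11 and -0.50. The call was lost after quantile normalization (-0.02, adjusted p = 0.616) and in the value table (-0.04, 0.308), and was absent within scan day 1 (0.795). Without a filter on dim probes the trend was called higher (adjusted p = 0.0113), against 0.005 per psi (0.574) with the filter.

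Monocyte genes of blood stood higher in exposed rats, with 10 of 13 positive, a median of 0.18 and 15 of 19 rats above the sham mean. Vcan (0.69 ± 0.28), the chemokine receptor Ccr2 (0.49 ± 0.23), the lipopolysaccharide co-receptor Cd14 (0.33 ± 0.19) and the Fc receptor Fcgr3a (0.35 ± 0.21) had the smallest p. At the preset correlation the adjusted p was 0.00622, with an adjusted p = 0.998 with an estimated correlation and an exact permutation p of 0.108. The median was 0.38 and 0.05 within the scan days and 0.09 with slide as a fixed block (adjusted p = 0.0174). The slides gave score differences of 0.05, 0.10, 0.11, 0.42 and 0.08. The call was lost within scan day 2 (adjusted p = 0.916) and without sham rat 509 (0.05, 0.252).

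B cell genes of blood likewise had 13 of 15 positive, a median of 0.18 and 16 of 19 rats above the sham mean. RT1-Ba of MHC class II (0.59 ± 0.36) and Ebf1 (0.38 ± 0.27) were among them, whereas Vpreb1a of the pre-B cell receptor lay at -0.25 ± 0.22. The preset adjusted p was 0.0254, with an adjusted p = 0.998 with an estimated correlation and an exact permutation p of 0.132. The median was 0.25 and 0.11 within the scan days and 0.12 with slide as a fixed block (adjusted p = 0.0474). The slides gave score differences of 0.35, 0.19, -0.25, 0.04 and 0.47. The call was lost without sham rat 507 (0.13, adjusted p = 0.404), 508 (0.13, 0.155) or 510 (0.06, 0.214), 15 psi rat 513 (0.14, 0.0967) or 20 psi rat 516 (0.16, 0.0677). It was also absent within each scan day (adjusted p = 0.0588 and 0.792), without a filter on dim probes (0.22, 0.105), with the stricter filter (0.05, 0.317) and with array weights (0.13, 0.112).

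Interferon-stimulated genes of blood had 21 of 26 positive, a median of 0.10, a mean of 0.19 and 14 of 19 rats above the sham mean. The antiviral genes Ifit2 (0.84 ± 0.32), Ifit3 (0.50 ± 0.24), Oasl (0.59 ± 0.32) and Bst2 (0.43 ± 0.27) had the smallest p. The brightest members lay near or below 0, Rsad2 at 0.02 ± 0.22, Irf7 at -0.23 ± 0.40 and Oas1b at -0.05 ± 0.17. Camera at its preset correlation gave an adjusted p = 0.00401, with an adjusted p = 0.998 with an estimated correlation and an exact permutation p of 0.356. The direction differed between batches, with a median of -0.06 on scan day 1 and 0.45 on scan day 2. The slides gave score differences of 0.20, 0.81, 0.67, -0.53 and -0.24. The list was called within scan day 2 (adjusted p = 0.000152) and not within scan day 1 (0.367), and its trend was called lower within day 1 (-0.021, 0.000131) and higher within day 2 (0.018, 0.00223). Slide as a fixed block gave 0.07 for any blast (adjusted p = 0.0108). The call was lost without sham rat 506 (0.11, adjusted p = 0.212) or 510 (0.04, 0.214).

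Along the overpressure, erythroid genes of blood had a positive slope in 18 of 18 cases, with a median of 0.023 per psi. The mitochondrial iron importer Slc25a37 (0.048 ± 0.022), the hemoglobin chaperone Ahsp (0.035 ± 0.018), the blood group antigen Rhd (0.039 ± 0.019) and the embryonic globin Hbz (0.034 ± 0.018) had the smallest p. This trend was called at the preset correlation (adjusted p = 2.17e-06), with an adjusted p = 0.998 with an estimated correlation and a permutation p of 0.0878. The score was 0 ± 0.38 (SD) in sham rats, -0.20 ± 0.30 at 15 psi, -0.06 ± 0.65 at 20 psi, 0.12 ± 0.16 at 25 psi and 0.20 ± 0.23 at 30 psi. Any blast against sham gave a median of -0.06 (adjusted p = 0.992) with a mean of 0.02. Its direction differed between the scan days, with a call lower within day 1 (-0.41, adjusted p = 0.011) and higher within day 2 (0.15, 0.00551), and it was called higher in the value table (0.0439). With an estimated correlation the adjusted p over all arrays was 0.999. The slope was 0.044 and 0.016 within the scan days and 0.026 with slide as a fixed block (adjusted p = 6.54e-06). Within the slides exposed rats differed from sham by 0, 0.70, 0.32, -0.28 and -0.83.

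Neutrophil genes of blood had negative slopes in 14 of 18 cases, with a median of -0.015 per psi. Lcn2 (-0.080 ± 0.028), Mmp8 (-0.068 ± 0.026), Ngp (-0.055 ± 0.022) and Mmp9 (-0.052 ± 0.030) had the smallest p. The preset adjusted p was 0.00484, with an adjusted p = 0.998 with an estimated correlation and a permutation p of 0.19. The score was 0.36 ± 0.45 (SD) at 15 psi and -0.14, 0.04 and -0.07 at the higher overpressures. The slope was -0.026 and -0.007 within the scan days and -0.022 with slide as a fixed block (adjusted p = 2.11e-05). Within the slides, each with 1 sham rat, the score of exposed rats differed from sham by -1.23, 0.02, 0.34, 0.78 and 0.11. The call was lost without 15 psi rat 511 (-0.018, adjusted p = 0.26) or 513 (-0.012, 0.0916), within scan day 2 (0.646), without a filter on dim probes (-0.015, 0.103) and with array weights (-0.024, 0.0507). For any blast the list was not called (median -0.02, mean 0.05, adjusted p = 0.898), but it was called higher within scan day 1 (0.42, 2.54e-05), against -0.30 within scan day 2. With an estimated correlation the adjusted p for any blast was 0.998.

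Cell cycle genes of blood had a median slope of 0.022 per psi with 16 of 25 positive. Bub1 (0.071 ± 0.030), Tyms (0.036 ± 0.019), Rrm2 (0.047 ± 0.026) and Tpx2 (0.063 ± 0.038), genes of mitosis and DNA synthesis, had the smallest p. Their trend had a preset adjusted p = 0.0191, with an adjusted p = 0.998 with an estimated correlation and a permutation p of 0.0535. The slope was -0.001 and 0.011 within the scan days and 0.016 with slide as a fixed block (adjusted p = 0.0105). Within the slides exposed rats differed from sham by -0.10, 0.56, 0.36, -0.36 and -0.26. The call was lost without 15 psi rat 511 (0.027, adjusted p = 0.308) or 514 (0.016, 0.0518) or 30 psi rat 528 (0.020, 0.197). It was also absent with normexp (0.014, adjusted p = 0.0639), in the value table (0.017, 0.0556), with the stricter filter (0.023, 0.25) and within scan day 1 (0.879). For any blast the list was not called (0.03, adjusted p = 0.971), but it was called lower within scan day 1 (-0.31, 0.0362). In the called blood lists, 0 members passed when adjusted over the list alone, and 0 over all genes tested.

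Other blood lists were not called for any blast over all arrays. Platelet genes had a median of -0.26 (camera adjusted p = 0.137, 10 of 14 negative), with the platelet chemokine Pf4 at -0.69 ± 0.32, Gp1bb at -0.40 ± 0.29 and Clec1b at -0.42 ± 0.32. T cell genes had a median of -0.07 (adjusted p = 0.898), with the receptor chains Cd3d at -0.17 ± 0.17 and Cd3g at -0.21 ± 0.21. Natural killer genes had one of 0.08 (adjusted p = 0.566), and were called higher within scan day 1 (0.32, 0.0102) and with array weights (0.0155). Heat shock genes lay at -0.08 (adjusted p = 0.137), with Hspa8 at -0.38 ± 0.18, and hypoxia-inducible and glycolytic genes at -0.13 (0.141). Immediate early genes lay at 0.08 (adjusted p = 0.338), with Jund at 0.32 ± 0.24, and inflammatory genes at 0.01 (0.898), with Il1b at -0.22 and Il1rn at 0.29. Inflammatory genes were called higher within scan day 1 (0.25, adjusted p = 0.0433). Without a filter on dim probes, platelet (adjusted p = 0.0191), heat shock (0.0143) and hypoxia-inducible genes (0.0341) were called lower, and natural killer genes higher for the trend (0.0172). Platelet genes were called lower for the trend with array weights (adjusted p = 0.0127). With an estimated correlation the smallest adjusted p of a blood list over all arrays was 0.998. Glucocorticoid-induced genes lay at 0 (adjusted p = 0.971) and p53 targets at 0.06 (0.678). Markers of brain injury had a median of -0.14 (adjusted p = 0.678, 11 of 16 negative), with the water channel Aqp4 at -0.33 ± 0.20, the synuclein Sncb at -0.32 ± 0.19 and the neuronal enolase Eno2 at -0.35 ± 0.24. Genes of neurodegeneration pathways had a median of 0.03 and a mean of -0.05 (adjusted p = 0.898). In the list of mechanosensing and junction genes, 1 member passed for the trend when adjusted over the list alone, the stretch-sensitive potassium channel Kcnk2 (0.111 ± 0.032 per psi), and 0 passed over all genes tested.

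No single probe was called in blood either, by limma over 18016 probes. At an unadjusted p under 0.05 there were 609 probes at 15 psi (279 higher), 1706 at 20 psi (1193 higher), 243 at 25 psi (150 higher) and 98 at 30 psi (52 higher), with 0 called in each. For any blast there were 335 (205 higher, 0 called) and for the trend 573 (360 higher, 0 called). The smallest adjusted p was 0.522 at 20 psi and 1 elsewhere. With slide as a fixed block the counts were also 0, and for any blast and the trend they were 0 within each scan day. With array weights, limma called 1121 probes at 15 psi, 1 for any blast and 201 for the trend, a setting that gave 15 psi rat 514 a weight of 5.41 and rat 511 one of 0.18. The unadjusted counts again depended on single rats. Without 15 psi rat 511 there were 2863 at 15 psi, 571 for any blast and 1941 for the trend, and without rat 515 there were 238 at 15 psi and 328 for the trend. Without rat 518 there were 1021 at 15 psi, 725 at 20 psi, 453 at 25 psi and 202 at 30 psi, and without rat 516 there were 2964 at 20 psi. The count at 25 psi was 150 without sham rat 506, and at 30 psi it was 60 without rat 530 and 217 without rat 529. By processing, array weights gave 5169 at 15 psi, 1975 at 25 psi, 624 at 30 psi, 1540 for any blast and 3669 for the trend. Slide as a fixed block gave 2968 at 20 psi, 183 at 30 psi and 520 for any blast. Quantile normalization gave 386 at 15 psi and 172 at 30 psi, where the value table gave 173. Without a filter on dim probes there were 5799 at 20 psi, 171 at 30 psi and 984 for the trend. The stricter filter left 695 at 20 psi, 64 at 30 psi, 215 for any blast and 375 for the trend, and the groups compared alone gave 786 at 25 psi and 266 at 30 psi. Within the scan days the counts ran from 182 to 1865.

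The genes named for blood from here on had the smallest p and did not pass. For any blast the adjusted p was 1 for all. The higher side held the ubiquitin ligase Rnf144b (0.84 ± 0.22 SE), Trafd1, which restrains innate immune signalling (0.80 ± 0.23), Samsn1 (0.72 ± 0.22) and Ripor2 (0.54 ± 0.17). The beta-glucan receptor Clec7a differed by 1.25 ± 0.33 and lay above background on 3 of 5 sham and 15 of 19 exposed arrays. Clec7a was the 1 probe called with array weights (1.51, limma adjusted p = 0.0316), and 1 of the 2 probes of Rnf144b and of Ripor2 had the direction given. The lower side held Banp (-0.50 ± 0.18), the complex I genes Ndufa12 (-0.68 ± 0.26) and Ndufb8 (-0.50 ± 0.20), Adat1 (-0.50 ± 0.20) and Ptprv (-1 ± 0.40, or -0.64 without sham rat 506).

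At 15 psi in blood the adjusted p was 1 for all genes named. Creld2, a gene of endoplasmic reticulum stress (1.41 ± 0.36), Plbd1 (0.71 ± 0.21), Proser1 (1.5 ± 0.48), Rnf144b (0.91 ± 0.29, by 1 of its 2 probes) and Samsn1 (0.88 ± 0.29) were on the higher side. The cation channel Trpm5 (-0.95 ± 0.27), Six2 (-0.80 ± 0.23), Shisa6 (-1.27 ± 0.38), neuromedin S (NMS, -0.93 ± 0.29) and Rundc3a (-0.59 ± 0.19) were on the lower side. Rat 511 lay above the other 15 psi rats for Proser1 and below them for Creld2, and without it the differences were 0.67 (adjusted p = 0.336) and 1.51 (0.293). With array weights, 8 of these genes passed, Rundc3a (-0.79, adjusted p = 0.000882), Shisa6 (-1.95, 0.00197), Creld2 (1.38, 0.00794), Rnf144b (1.13, 0.0111), Samsn1 (1.01, 0.0159), Trpm5 (-1, 0.0172), Plbd1 (0.58, 0.0285) and NMS (-0.90, 0.0374). At 20 psi the adjusted p was 0.522 for all. The sortilin-family receptor Sorcs2 (at least 3.49-fold) and the G protein subunit Gna14 (at least 3.32-fold) were higher and not well above background in any sham rat. They stood beside Qrfpr (1.25 ± 0.31), the transcriptional repressor Tgif2 (1.24 ± 0.31, with 2 of its 3 probes in this direction) and Trafd1 (1.12 ± 0.29). The deubiquitinase Usp9x (-1.09 ± 0.31), Pcyox1l (-1.34 ± 0.40), Itgb1bp1 (-1.01 ± 0.31), Zfp410 (-1.39 ± 0.44) and the calcium pump Atp2b3 (-1.05 ± 0.33) were on the lower side. Among the 20 psi arrays, that of rat 518 stood most apart at the ends of the range for Qrfpr, Tgif2, Trafd1, Usp9x, Pcyox1l and Atp2b3. It lay at -0.47 for Qrfpr, -0.58 for Tgif2 and -0.67 for Trafd1, and at -3.18 for Usp9x, -3.6 for Pcyox1l and -3.01 for Atp2b3. The differences of these genes may rest in part on that array. Its high reading at dim probes would raise low values, so it does not by itself account for the genes on the lower side.

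At 25 psi in blood the adjusted p was 1 for all genes named. The higher side held Clec7a (1.43 ± 0.41), Rnf144b (0.93 ± 0.28, by 1 of its 2 probes), Ifit2 (1.37 ± 0.41), the MHC class I gene RT1-N3 (0.76 ± 0.23) and Plbd1 (0.62 ± 0.20). On the lower side were Sag (-0.68 ± 0.23), the matrix protein Fbln1 (-1.94 ± 0.73), Utf1 (at least 1.79-fold), Slc38a8 (-0.74 ± 0.29, or -0.48 without rat 521) and Hes3 (-0.97 ± 0.39). At 30 psi (adjusted p = 1) Clec7a (1.43 ± 0.41), Plvap (0.90 ± 0.27), the mitochondrial folate enzyme Mthfd2 (0.70 ± 0.24), Rnf144b (0.80 ± 0.28) and the deubiquitinase Bap1 (0.74 ± 0.28) led the higher side. Dbil5 (-1.23 ± 0.42), Col23a1 (at least 2.13-fold), Hsbp1l1 (at least 2.01-fold), St8sia1 (-1.19 ± 0.45) and Mtdh (at least 1.88-fold) led the lower side. For the trend (adjusted p = 1) the positive slopes per psi were those of Steap2 (0.080 ± 0.020), Zfp746 (0.063 ± 0.017), Ddah1 (0.065 ± 0.018), Kcnk2 (0.111 ± 0.032) and NMS (0.062 ± 0.018). The negative ones were those of Fam120a (-0.063 ± 0.017), Pik3r1 (-0.059 ± 0.018) and Nsdhl (-0.049 ± 0.016). Sorcs2 and Rnase17 had a negative sign, but lay above background on 3 and 6 of 19 exposed arrays and on 0 at 25 and 30 psi, so no slope is given. Array weights made 5 of these slopes pass, those of Pik3r1 (-0.084, adjusted p = 0.00812), Steap2 (0.082, 0.0208), Ddah1 (0.083, 0.0236), Fam120a (-0.063, 0.0236) and Kcnk2 (0.116, 0.0459).

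Whether the response differed between the tissues was tested by the interaction of tissue and any blast over the 15903 probes measured in both. Limma called 0 probes, with 357 at an unadjusted p under 0.05 (152 higher in hair), or 585 without hair sham rat 382. The unadjusted count was 602 without rats 384 and 518, 1225 with array weights, 763 without a filter on dim probes and 178 with the stricter one, with 0 called in each. The smallest adjusted p was 0.999, which holds for all genes named next. The response was higher in hair for Banp (0.98 ± 0.26 SE), Lyl1 (0.99 ± 0.28), the semaphorin Sema4d (1.33 ± 0.41) and the lysosomal gene Cln6 (1.28 ± 0.42). It also had a positive sign for Agrp, given without a value because the hair sham arrays were at background. It was lower in hair for the integrin Itgb5 (-1.47 ± 0.40), the matrix proteoglycan Aspn (-1.88 ± 0.56), the oxygen-sensing hydroxylase Egln2 (-0.59 ± 0.18), Tm4sf19 (-1.54 ± 0.48) and Rims3 (-0.71 ± 0.23). A list called in 1 tissue alone is therefore not shown to differ between them.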

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

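The tests of rats 384 and 518 and that of genes varying together were chosen only after the results were seen, and those of rat 384's missing cells and rat 518's cell mix replaced earlier ones; the splits of the arrays were set beforehand. Scan day was chosen as an alternative after the data were seen, and the limits of its test in both tissues after the result.

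Hair sham rat 384 stood apart from the other hair arrays. Its median correlation with them was 0.927, against at least 0.963 for the other 23, and its gap to the nearest sham rat was 0.789 of the group's range; the median log2 difference of a list's genes from their medians over all other hair arrays was -2.86 for hair shaft genes (-0.65 to 1.1 for the other arrays, each taken the same way) and -3.82 for melanocyte genes (-2.42 to 0.94). Weak labelling alone is argued against, since another array of similar or lower signal correlated at 0.97 with the rest. A sample with fewer hair shaft and pigment cells remains open: of the genes over 4-fold lower on this array, 44.2% were at least 2-fold higher in hair than in blood, against 34.5% of all such genes and 13.8% of those over 4-fold higher, a difference too small to decide; an earlier reading, that 715 genes outside the marker lists over 4-fold off (highest other array 177) excluded it, was dropped because 650 of them were lower, as a loss of cells would also give. A blood sample under a hair label is argued against, since the median correlation with the blood arrays was 0.599, below that of every other hair array (0.605 to 0.653) and below that with the hair arrays. A wrong group label or a sample of other origin remains open: the medians with the hair groups ran from 0.922 to 0.932 with none standing out, but only 2 of the other 23 arrays correlated best with their own group, so group membership cannot be read from these values. No biological explanation was tested, since the array lies within the sham group.

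Blood 20 psi rat 518 stood apart by its 75th percentile of signal (361.9, gap ratio 0.929), its median signal (188.9, 0.855), its median correlation with the other blood arrays (0.889, ratio 0.72, others at least 0.953) and its erythroid score (-1.19, ratio 0.759). High background on the array would give such values. The 6568 probes not well above background on any other blood array had a median processed signal of 89.1, against 4.3 to 15.4 elsewhere. These probes were chosen for being dim on the other arrays, with rat 518 exempt. The choice holds the other arrays low, and no other array was exempted in turn, so the size of this gap cannot decide. That signal has the background already subtracted, and the background itself was not tested. The scale of the array was compressed, with a slope of 0.70 on the mean of the other arrays (others 0.95 to 1.06). A different mix of blood cells remains open, because 3 of 7 lists of blood cell types lay below the other arrays' range by the same median difference, but a compressed scale moves every list and makes that test void. The exposure of this rat was not tested as a cause, since a single rat cannot separate array from exposure.

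The gene lists called at the preset correlation, 6 in hair and 8 in blood, were weighed as a 3rd pattern. Genes of a list that vary together between rats whatever their exposure may produce such calls: with an estimated correlation 0 lists were called in both tissues together, and at the preset correlation 68 of 100 splits of the hair arrays called at least as many (highest other 17) and 64 of 100 of the blood arrays (highest other 19), so chance cannot be excluded. In blood 0% of the calls were lost with scan day as a covariate, although it alone accounted for 1356 probes. Each group was split over both days, so such a covariate could move the contrasts little. It also cannot account for responses that differ between the days. Scan day therefore stays open in blood. In hair it stays open: 16.7% of the calls were lost, that of hypoxia-inducible and glycolytic genes (median -0.11 before and -0.09 after, adjusted p = 0.0354 and 0.0621), but scan day accounted for 0 probes there, so the covariate moved little and the test decides nothing. A response to the shockwave stays open and untested beyond these values.

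No count of single probes in exposed against sham rats could be told from other splits of the same arrays. In hair, the number at an unadjusted p under 0.05 was as large as the real one in 98 of 100 splits at 15 psi (real 192, highest other 4332), 69 at 20 psi (679, 3935), 57 at 25 psi (1127, 4843), 65 at 30 psi (610, 5049), 56 for any blast (705, 3861) and 60 for the trend (426, 4103). In blood it was so in 40 of 100 splits at 15 psi (609, 4178), 16 at 20 psi (1706, 2989), 48 at 25 psi (243, 988), 85 at 30 psi (98, 1023), 65 for any blast (335, 6961) and 48 for the trend (573, 4410). For the difference between tissues it was 71 of 100 (357, 2939), with groups reassigned in each tissue apart, so that both arrays of a rat were not kept together. With array weights refitted for each split, 10 of 100 called as many probes as the 1121 of blood at 15 psi (highest other 5736) and 28 as many as the 201 of the blood trend (8777). The highest any-blast split of hair, which called 301 probes, put rats 384, 387, 394, 511 and 523 in the place of sham, and that of blood, which called 4330, put rats 507, 511, 517, 518 and 524 there, arrays of both scan days. Few any-blast splits called any probe, 5 of 100 in hair and 1 of 100 in blood, against a real number of 0. The splits named above were picked as the highest, so they do not show a structure of the samples, which was not tested. For hair against blood in sham rats, 1 of 100 splits was as large, the real one (17730, highest other 14060). The other splits mix both tissues and still hold part of the tissue difference, so they are not a measure of chance.

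Chance alone flags about 1 in 20 groups as holding a sample far from the others: among 40 groups of array measures 7 held one, among 60 of list scores 4 and among 156 of gene levels 7. Hair 20 psi rat 516 had the highest median signal of its group (99.2, gap ratio 0.893) and the highest share of probes above background (71.0%, ratio 0.879). Blood 25 psi rat 523 lay apart in the share of probes above background (50.5%, ratio 0.724). The monocyte score of blood sham rat 509 was -0.27 (ratio 0.785). The ribosomal protein score was -0.39 in blood sham rat 510 (ratio 0.758) and -0.54 in 15 psi rat 511 (0.838). Among named genes, Ptger3 lay at -4.65 in hair 15 psi rat 387 (0.77), and in blood 15 psi rat 511 Creld2 lay at -2.15 (0.843) and Proser1 at 0.99 (0.896). In blood sham rat 509 RT1-N3 lay at -0.46 (0.847) and Mtdh at -2.20 (0.744). Fbln1 lay at -2.15 in blood 25 psi rat 524 (0.737) and Dbil5 at -4.26 in 30 psi rat 528 (0.797).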

How the results depend on the processing

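Scan day, normexp on the median signal, the permutation of whole rats and the removal of rats 384 and 518 were chosen after the data were seen; the other alternatives were fixed beforehand. Where a value departs below, the cause was not tested. Counts of called probes stayed at 0 in every blast comparison except as follows. Array weights called 1121 probes in blood at 15 psi (465 higher, 656 lower), 1 for any blast and 201 for the trend (126 higher, 75 lower), the arrays of scan day 2 alone called 2 in blood at 30 psi (Rhag at 2.31, adjusted p = 0.0427, and a probe without a symbol at 3.89, 0.0255, named after their values were seen), and over the arrays left out hair gave 0 to 1 both at 25 psi and for any blast, the 1 being Depp1 without sham rat 506.

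The number of lists called in hair was 11 with normexp, 3 in the rats under 500 alone and 0 both with an estimated correlation and with whole rats permuted, and 4 (without 30 psi rat 526) to 11 (without sham rat 506) over the arrays left out; in blood it was 0 with an estimated correlation and 0 with whole rats permuted, and 7 to 11 over the arrays left out. Without rats 384 and 518 it was 7 in hair and 8 in blood. Of 208 values of called lists, 147 kept direction and call, 52 kept only the direction and 9 turned; with single arrays left out 311 of 336 kept both and 25 only the direction. Those that turned were ribosomal protein genes of hair for any blast, at 0.04 in the value table, 0.03 with array weights and 0.02 in the rats under 500, and for the trend, at 0.001 with the rat number series as a covariate and 0.003 in the rats under 500. In the rats under 500 the hair trends also turned for the cell cycle (-0.002) and the respiratory chain (0.003), and within scan day 1 of blood interferon genes (any blast, -0.06) and the cell cycle (trend, -0.001).

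Of 1663 values of named genes, 1646 kept direction and side of the threshold, 14 passed in addition, all in blood with array weights (8 at 15 psi, 1 for any blast, 5 for the trend), and 3 turned, all with normexp: Scara5 at 30 psi (-0.04) and for any blast (-0.05) and Dnd1 for any blast (-0.04). Leaving out single arrays kept 3316 of 3318. None of these genes was called in the main fits, and all were picked for a small p in the same data. Staying uncalled with the same sign is therefore little evidence that their differences are stable. In sham rats, 126 of 126 marker values kept direction and call, 576 of 576 with single arrays left out; probes called were 6913 with the stricter filter, which tested 8819, and 17234 to 18018 over the arrays left out. The replicate block, which pairs the tissues of a rat, gave 17730 (7857 higher and 9873 lower, against 7858 and 9872) and 0 for the interaction. Normexp on the mean signal and the rats under 500 in blood were not run, the first since no such column was used here and the second since no blood array has such a number. Signal over background limited the probes tested, of 30367, to 20673 in hair and 18016 in blood.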

Other observations

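The tests in this part were chosen beforehand. In sham rats the pathways of the 2 tissues also differed, in a fit in which the median over all probes was -0.24 and moved between -0.57 and 0.29 with the scaling, and to -1.23 without a filter on dim probes. Genes of hair cycle signalling were called higher in hair in 22 of 32 cases (3 lower, median 2.16, or 2.14 with bounds), with the transcription factor Ovol1 24.3-fold higher (4.60 ± 0.36, limma adjusted p = 1.1e-15), the receptor Notch1 10.9-fold (3.45 ± 0.25, adjusted p = 7.46e-17) and Dlx3 10.4-fold (3.38 ± 0.40, adjusted p = 2.08e-10). Mechanosensing and junction genes were higher in 16 of 24 cases (7 lower, 2.02). Among their brightest members, the gap junction protein Gja1 was at least 899-fold higher (limma adjusted p = 2.65e-32). Gjb2, also of gap junctions, was 243-fold higher (7.92 ± 0.25, adjusted p = 1.54e-30) and the junction protein Jup 47.4-fold (5.57 ± 0.17). Heat shock genes were higher in 15 of 19 cases (2 lower, 1.21), with the small heat shock protein Hspb1 231-fold higher (7.85 ± 0.27, adjusted p = 6.92e-29), and endoplasmic reticulum stress genes in 13 of 19 (4 lower, 1.64), with the chaperone Hspa5 9.75-fold higher (3.29 ± 0.22). Interferon-stimulated genes were lower in hair in 24 of 29 cases (1 higher, -2.63, or -2.56 with bounds), with Rsad2 2860-fold (-11.48 ± 0.73, adjusted p = 7.36e-19) and Irf7 79.0-fold lower (-6.30 ± 0.44), while Oas1b differed by -0.19 ± 0.26 (adjusted p = 0.522). Cell cycle genes were lower in 18 of 31 cases (6 higher, -0.85), with Ube2c 89.0-fold (-6.48 ± 0.27) and E2f1 34.9-fold lower (-5.12 ± 0.27). Respiratory chain subunits were higher in 35 of 52 cases (12 lower, 1.13), but the brightest of them, Cox6a1 (-2.53 ± 0.23), Ndufa1 (-3.23 ± 0.20) and Uqcrh (-2.90 ± 0.18), were lower. Ribosomal protein genes were divided, 16 higher, 9 lower and 22 of 47 not called (0.19).

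The remaining lists were not called for any blast against sham. In hair, medians were -0.04 for apoptosis and autophagy (camera adjusted p = 0.445), 0.03 for matrix remodelling (0.928, with a mean of 0.01 and a negative test), 0.04 for coagulation and vascular tone (0.928), -0.01 for mechanosensing and junctions (0.928, mean 0.02 and positive test) and 0.18 for Merkel cells (0.928). Of the cell types outside the follicle epithelium, Schwann cell genes of hair lay at -0.05 (0.894), skeletal muscle at 0.01 (0.894, mean -0.03), erythroid genes at 0.01 (0.894, mean -0.14), neutrophil genes at 0.04 (0.928), T cell genes at 0.04 (0.928, with a negative test), natural killer genes at -0.02 (0.509, mean 0.13) and platelet genes at 0.11 (0.623). In blood, antioxidant genes lay at -0.08 (0.527), apoptosis and autophagy at -0.03 (0.992) and mechanosensing genes at 0.03 (0.898). In hair Herpud1, a gene of endoplasmic reticulum stress, differed by 0.63 ± 0.19 and did not pass; it is named after its values were seen.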
